A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

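Total RNA of 4 yeast libraries was sequenced by the authors: wild type and a pho23 deletion of strain SEY6210, each growing in YPD and after 2 h in SD-N. Per the submitters' processing notes, bases were called with CASAVA 1.8.2 and reads were aligned to sacCer3 (R64) with Bowtie2 2.1.0. The deposited values are RPKM per ORF, made by the authors from the aligned reads. The counting tool, the annotation and the use of strand are not given in the sources used here, so overlapping and antisense ORFs are uncertain. All 6678 ORFs of the table were used. Symbols, lengths and positions came from the RefSeq table for R64, which holds 5997 of these ORFs. The other 681 carry the deposited name and have no length here.

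The summed RPKM was 1101484 for growing wild type, 1097556 for the growing deletion, 883544 for starved wild type and 976219 for the starved deletion. In the same order, 22, 27, 16 and 17 ORFs were listed at 0, and 5195, 5313, 5869 and 5793 reached an RPKM of 10. Read numbers were estimated from the commonest value of RPKM times length in kb below 0.06, refined over values close to it and taken as a single read. With this step, 35.9%, 40.5%, 43.1% and 41.5% of the values below 100 reads fell within 0.1 of a whole number, against 20.0% by chance. With a step 3% off, the shares were 23.2%, 23.2%, 20.7% and 20.3%. Some of the same values had set the step, and the limit of 0.06 left larger steps, and so lower depths, unsearched. The estimate is therefore rough. Counting intervals (95%, binomial) use it and cover counting error only.

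Folds were computed as log2((RPKM + 1)/(RPKM + 1)) on the values as deposited, without further scaling. With 1 library per group there are no replicates to test within a comparison, and a fixed rule of size was used. An additive fit over all 4 libraries was not run. An ORF was eligible at an RPKM of at least 10 in at least 1 of the libraries compared, and was counted at 2-fold or more. The 4 comparisons were deletion against wild type in growing cells, the same in starved cells, and starved against growing cells in each genotype. The difference between both starvation folds was computed over all 4 libraries. Overlaps are given beside the number that independent lists would share.

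For each gene list, the median log2 fold of all measured members, counted at any RPKM, was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. These percentiles describe the libraries and are not tests across cultures. The 29 lists were PHO23 and Rpd3 complex subunits, core autophagy, selective autophagy with the cytoplasm-to-vacuole pathway, autophagy transcription regulators, vacuolar hydrolases, nitrogen catabolite repression targets, amino acid biosynthesis, and sulfur and methionine genes. Cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, phosphate regulon, early meiotic genes, general stress response, glycolysis and fermentation, TCA cycle and respiratory chain, hexose transporters and proteasome followed. The rest were the iron regulon, ergosterol biosynthesis, histones, G1 and S phase genes, G2 and M phase genes, a-specific, alpha-specific and haploid-specific genes, strain marker loci, and the PAU and COS families. Another 3 lists were added after the data had been seen: 21 pheromone-response genes, the 8 of them whose values had not yet been looked at, and 19 single-copy cytosolic ribosomal protein genes. ENB1, HIS3, TRP1 and SUC2 were missing under these symbols and were not analysed here.

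The groups, comparisons, thresholds, 29 lists, alternatives and the rule for naming genes were set before the data were examined. The rule names the 10 highest and 10 lowest eligible ORFs of each comparison, of both conditions together and of the difference of starvation folds. It adds PHO23, every core autophagy gene, and up to 4 members of each other list with the largest fold in the comparison described. Not every ORF that the rule names is given in the text. Members of near-identical families are named as uncertain. Alternatives were pseudocounts of 0.1 and 5, no filter, an RPKM of at least 30, and scaling by median of ratios, by equal sums or by upper quartile.

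The procedure was tested on simulated data of 5997 ORFs at the estimated depths, with 200 changed ORFs and a dispersion of 0.01. In both genotype comparisons, 100% of the 4-fold changes and 4.0% of the 1.5-fold changes were counted at 2-fold. The changes were planted only in ORFs with a mean RPKM of at least 20, so recovery at lower levels was not covered. At most 1 unchanged ORF was counted. The dispersion was assumed, without replicates behind it, so this number does not measure false calls between separate cultures. Of 100 random lists of 23 ORFs, 4.0% fell outside the central 95% of the matched lists, and 100% did so on the upper side after a shift of 0.8 was added. These were random ORFs, so the share does not hold for lists of genes that vary together. A simulation of counting error alone at the measured levels, over 20 draws, gave 0 ORFs of 5057 in growing cells and 0 to 1 of 5524 in starved cells. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.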

Results

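Transcript levels were measured by sequencing total RNA from budding yeast, Saccharomyces cerevisiae, of the laboratory strain SEY6210. This strain is haploid and of mating type alpha. Wild-type cells were set beside cells lacking PHO23, which encodes a subunit of the Rpd3L histone deacetylase complex. Each genotype was sampled in rich medium (YPD) during mid-log growth and after 2 h in a medium without nitrogen (SD-N). Starvation below stands for this whole change of medium. Loss of nitrogen cannot be told apart from other differences between YPD and SD-N. The 2 genotypes and 2 conditions give 4 groups with 1 library each, so that no difference below has a replicate check. The table lists 6678 open reading frames (ORFs) as RPKM, a read count scaled by ORF length and library size. Their RPKM summed to 1101484 in growing wild type, 1097556 in the growing deletion, 883544 in starved wild type and 976219 in the starved deletion. The step among the lowest values corresponds to a rough estimate of 23000000, 27500000, 19600000 and 21800000 reads in the same order. Fold changes are log2 of the ratio of (RPKM + 1), which understates the change of low genes. An ORF is counted as higher or lower at 2-fold, with an RPKM of at least 10 in at least 1 of the libraries compared. Members of the gene lists are counted at any RPKM.

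PHO23 itself (YNL097C, R64 assembly, chromosome XIV, 441366 to 442358) stood at an RPKM of 12.3 in growing wild type and 0.13 in the growing deletion. After starvation the values were 23.4 and 0.0546. The genotype labels of all 4 libraries therefore fit the level of the deleted gene. The other subunits in the 14-gene list of Rpd3 complex members showed no common direction. With PHO23 included, the list median was -0.01 in growing cells and 0.10 in starved cells, the latter turning to -0.03 when libraries were scaled to equal sums. UME6, which encodes the DNA-binding repressor that recruits the complex, had genotype log2 folds of 0.83 growing and 1.25 starved. ASH1, a repressor of mating-type switching, was at 1.13 in starved cells.

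In growing cells the deletion library held more transcript of most autophagy genes. The comparison asks whether transcripts of the autophagy machinery differ when Pho23 is missing and nitrogen is plentiful. Of the 23 core autophagy genes, 22 had a log2 fold above 0 and 8 were at least 2-fold higher (4 with a pseudocount of 5), none 2-fold lower. The list median was 0.81, with quartiles of 0.42 and 1.12, above all 10000 random lists matched on expression (percentile 100). Other lists were as extreme here: general stress, early meiotic and amino acid biosynthesis genes (medians 0.66, 0.56 and 0.23) also stood at percentile 100. Cytosolic ribosomal proteins (median -0.06) were at 0.0, so the percentile does not measure the size of a shift. ATG7, encoding the E1-like enzyme of the ubiquitin-like conjugation systems, had an RPKM of 4.25 in wild type and 19.5 in the deletion (log2 fold 1.97). ATG29, part of the scaffold that starts autophagosome formation, was at 5.26 and 21.8 (1.86). ATG14, a subunit of the autophagy-specific phosphatidylinositol 3-kinase complex, was at 5.94 and 20.2 (1.61). ATG8, whose protein is joined to lipid on the growing membrane, was at 20.6 and 48.8 (1.20). ATG9, the membrane protein of the vesicles that seed autophagosomes, had a log2 fold of 1.33, and ATG1, the kinase that starts the process, of 1.30. Both lay under an RPKM of 10 in each growing library, at 2.81 and 8.59 for ATG9 and 2.62 and 7.92 for ATG1. ATG4, the protease that processes Atg8, stood at 1.03 and ATG13, the regulatory partner of Atg1, at 1.0. Those under 2-fold included ATG17 at 0.85, ATG3 and ATG18 at 0.84, ATG22 at 0.81, VPS15 at 0.70, ATG15 at 0.69 and ATG16 at 0.68. VPS30 was at 0.54, ATG2 at 0.43, ATG31 at 0.41, VPS34 at 0.40, ATG5 at 0.38, ATG38 at 0.32 and ATG12 at 0.06. ATG10 alone was below 0, at -0.79.

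**Figure D1:**
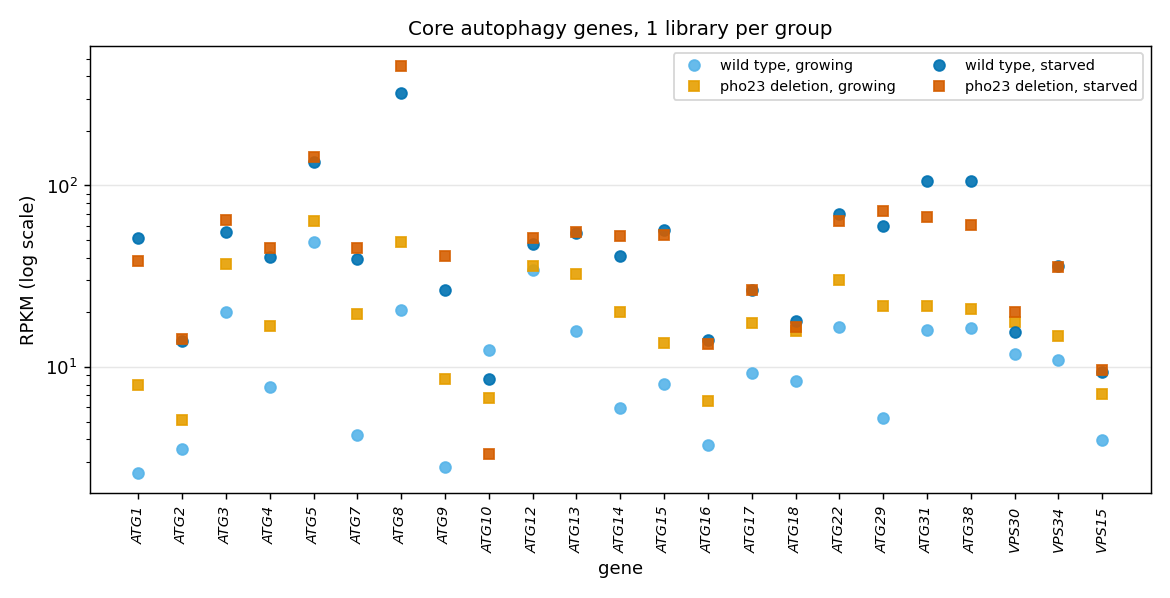
RPKM on a log scale of the 23 core autophagy genes, with 1 point per library and 1 library per group (circles, wild type; squares, pho23 deletion; pale, growing; dark, starved). In growing cells the deletion lies above wild type for 22 genes, and after starvation the genotypes lie close together, with a list median of 0.03 that turns to -0.11 under equal-sum scaling.

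Counting intervals of these ratios excluded 1 for each of the 8 genes. The RPKM ratio of deletion to wild type was 4.59 for ATG7 (95% interval 3.92 to 5.40), 4.14 for ATG29 (3.22 to 5.33) and 3.40 for ATG14 (2.82 to 4.12). ATG7 lies on chromosome VIII (YHR171W, 445713 to 447605), ATG29 on XVI (YPL166W, 237338 to 237979), ATG14 on II (YBR128C, 493081 to 494115) and ATG8 on II (YBL078C, 80378 to 80731). These intervals rest on the estimated depth and cover counting error only.

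Genes of selective autophagy and the cytoplasm-to-vacuole pathway were also higher. Among 16 such genes, 6 were at least 2-fold higher (3 with a pseudocount of 5) and 15 above 0 (median 0.65, percentile 100). ATG40, an autophagy receptor of the endoplasmic reticulum, was at 1.52, ATG33 at 1.44, ATG34 at 1.26 and ATG19, the receptor for vacuolar aminopeptidase, at 1.17. All 12 vacuolar hydrolases were above 0 (median 0.42), with 3 of them at least 2-fold higher, or 1 with a pseudocount of 5. The 3 were ATG42 (YBR139W), a carboxypeptidase, at 1.91, ATH1, an acid trehalase, at 1.74 and APE1, an aminopeptidase, at 1.08. Transcription factors known to act on autophagy genes had a median of 0.11 over 14 genes, none at 2-fold.

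Several other groups also differed between genotypes in growing cells. General stress genes had a median of 0.66, with 9 of 30 at least 2-fold higher, led by YGP1 at 2.02, HSP42 at 1.79, MSC1 at 1.78 and GAD1 at 1.67. HXK1 was at -1.11, and SPI1, named after its value was seen, at -1.27. Early meiotic genes, classic targets of Ume6 and Rpd3, had a median of 0.56 and 7 of 20 at least 2-fold higher, against 0.35 and 3 with a pseudocount of 5. MND1, for meiotic recombination, was at 2.90, SAE3 at 1.92 and REC114 at 1.40, while MSH5 was at -2.26. The phosphate regulon had a median of -0.39, with 3 of 17 at least 2-fold lower. These were PHO89, a phosphate transporter, at -2.51, SPL2 at -1.21 and GIT1 at -1.17, and a pseudocount of 5 left 1. SPL2 and GIT1 lay under an RPKM of 10 in both growing libraries. The 2 genes above 0 were PHO8 at 0.99 and PHO5 at 0.40. Targets of nitrogen catabolite repression had a median of -0.23. Among them DCG1 was at -2.15, UGA4, a GABA permease, at -1.38 and DAL1 at -1.24, with UGA1 at 1.25. DAL4 at -1.22 and DAL2 at -1.13, named after their values were seen, complete the 5 that were 2-fold lower, of which a pseudocount of 5 leaves 1. Cytosolic ribosomal protein genes differed little, with a median of -0.06 and none of 137 at 2-fold. Mitochondrial ribosomal protein genes were at -0.07 and ribosome biogenesis genes at -0.20, again with none at 2-fold.

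Across all genes, 5439 ORFs were eligible in growing cells, with 215 at least 2-fold higher and 113 at least 2-fold lower in the deletion. Beside MND1, the highest folds included those of GPC1, a glycerophosphocholine acyltransferase (2.77), YJL163C (2.65), FMP23 (2.43), YOL131W (2.41), CPP3 (2.37), STR3, a cystathionine beta-lyase (2.37), UGX2 (2.33) and VPS73 (2.27). STR3 and MND1 are neighbours, 530 bp apart. Counting error alone, simulated at these levels and depths, gave 0 such ORFs in 20 draws. The split moved to 172 higher and 163 lower with median-of-ratios scaling and to 180 and 150 with upper-quartile scaling.

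Mating genes were lower in the deletion in both conditions, and they supplied most of the lowest folds. Growing cells lacking PHO23 had an RPKM of 3.82 for AGA1, a subunit of the a-agglutinin, against 317 in wild type (log2 fold -6.05; ratio 0.012, interval 0.0105 to 0.0137). FIG1, needed for mating projections, was at 0.595 against 65.0 (-5.37), and FUS1, for cell fusion, at 2.38 against 96.1 (-4.84). PRM6 was at -4.03, PRM1, for fusion of the plasma membranes, at -3.43 and MFA2 at -3.37. YML047W-A, an ORF that lies at the PRM6 locus by its name and is uncertain for that reason, was at -3.29. Of the 4 alpha-specific genes, all were at least 2-fold lower. MF(ALPHA)2, an alpha-factor gene, had an RPKM of 1745 in wild type and 55.6 in the deletion (-4.95). SAG1, the alpha-agglutinin, was at 682 and 31.2 (-4.41), STE3, the receptor for a-factor, at -2.27 and MF(ALPHA)1 at -1.42. After starvation the alpha-specific values were -4.78 for MF(ALPHA)2, -2.80 for SAG1, -2.35 for MF(ALPHA)1 and -1.89 for STE3. A list of 21 pheromone-response genes, drawn up after these values had been seen, had medians of -1.73 growing and -2.00 starved. In each condition 16 of them were at least 2-fold lower, 14 of them in both.

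**Figure D2:**
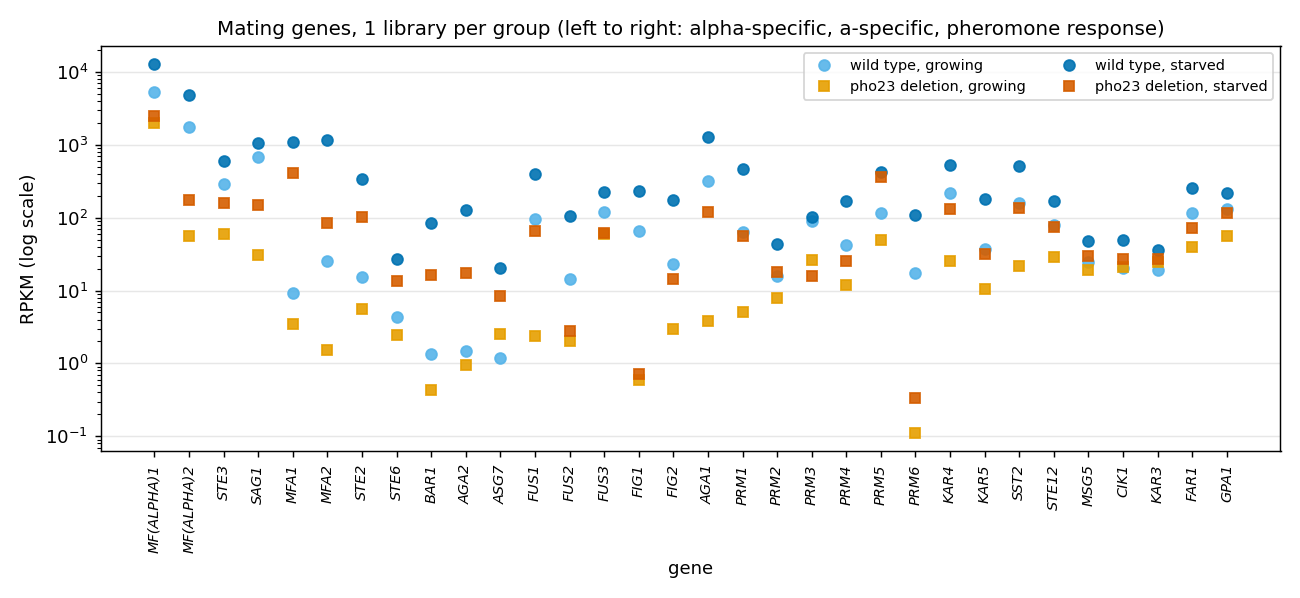
RPKM on a log scale of alpha-specific, a-specific and pheromone-response genes, with 1 point per library and 1 library per group (circles, wild type; squares, pho23 deletion; pale, growing; dark, starved). FIG1 and PRM6 stayed under an RPKM of 1 in both deletion libraries, while wild type reached 234 and 109 after starvation.

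The a-specific genes, normally silent in alpha cells, were low in growing wild type and far higher after starvation in both genotypes. MFA1, encoding a-factor, had an RPKM of 9.31 growing and 1106 starved in wild type, against 3.51 and 406 in the deletion. MFA2 was at 25.1 and 1178 in wild type and at 1.52 and 83.6 in the deletion. All 7 a-specific genes were at least 2-fold higher after starvation in each genotype, with medians of 5.16 and 3.62. Several growing values lay near 0, and with a pseudocount of 5 the medians were 4.08 and 1.99, with 6 genes at 2-fold in the deletion. AGA2 was at 5.70 and BAR1, a protease that degrades alpha-factor, at 5.16 in wild type. Between starved genotypes the median log2 fold of the 7 genes was -1.72, with 6 of them at least 2-fold lower in the deletion and STE6 at -0.92. AGA2 stood at -2.83, BAR1 at -2.27 and STE2, the receptor for alpha-factor, at -1.72. Among 6 haploid-specific genes the medians were -0.43 growing and -0.93 starved. FAR1, which arrests the cycle in response to pheromone, was at -1.54 and -1.84, and GPA1, the G protein alpha subunit, at -1.24 and -0.93. STE4 was at -1.06 in starved cells and RME1, a repressor of meiosis, at 1.09 in growing cells.

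After starvation the ribosomal protein genes separated the genotypes most broadly. The comparison asks how the deletion bears on transcript levels once nitrogen is gone. Of 137 cytosolic ribosomal protein genes, 132 were at least 2-fold higher in the starved deletion than in starved wild type, and all 137 were above 0. The median was 1.44, with quartiles of 1.32 and 1.57 (percentile 100). RPS26B was at 2.18, RPS22A at 2.08, RPS3 at 2.00 and RPL43B at 1.96. The 5 under 2-fold, named after their values were seen, were RPS28A at 0.95, RPP1A at 0.93, RPS27A at 0.89, RPL4B at 0.66 and RPL4A at 0.64. Many of these genes are near-identical pairs whose reads could be split, so single paralogs are uncertain. Ribosome biogenesis genes had a median of 0.84, with 18 of 66 at least 2-fold higher (28 with median-of-ratios and 10 with equal-sum scaling). Among them HAS1, an RNA helicase, was at 1.78, NSR1 at 1.29 and both NOP7 and NUG1 at 1.26. Mitochondrial ribosomal protein genes had a median of -0.06, which turned to 0.04 with median-of-ratios scaling.

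The core autophagy genes, in contrast to growing cells, had a starved genotype median of 0.03 (-0.11 with equal-sum scaling), with 22 of 23 under 2-fold. ATG10 was at -1.14, ATG38 at -0.80, ATG31 at -0.65, ATG1 at -0.40, ATG8 at 0.49 and ATG9 at 0.61. ATG8 had an RPKM of 322 in starved wild type and 453 in the starved deletion. The selective list was at 0.01 (-0.13 with equal-sum scaling) and the vacuolar hydrolases at -0.05 (0.05 with median-of-ratios scaling), with none at 2-fold in either. Whether the genotype effect differs between conditions could not be tested with 1 library each.

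Medians of several metabolic, stress and meiotic groups also lay off 0 in starved cells. Glycolysis and fermentation genes were at -0.53, none of 16 at 2-fold, with ADH1 at -0.87 and both PGK1 and ENO2 at -0.85. Genes of the TCA cycle and respiratory chain were at -0.30, none of 38 at 2-fold. Amino acid biosynthesis genes were at -0.37, with ARG3, of arginine synthesis, at -1.25 and ARG8 at -1.21 the 2 of 40 at 2-fold. General stress genes were at -0.20, with GPH1 at -1.30, HXK1 at -1.27, SSA4 at -1.26 and DDR2 at -1.22. Nitrogen catabolite repression targets were at -0.27, UGA4 at -2.85. Phosphate genes were at -0.34, with PHO89 at -1.50. PHO11 at -1.38 and PHO12 at -1.35 are near-identical and uncertain, and PHM8 was at -1.02. Of these 4 phosphate genes, a pseudocount of 5 left 2 at 2-fold. The regulators of autophagy genes were at -0.16, with UME6 at 1.25. With median-of-ratios scaling these negative medians lay nearer to 0, and with equal-sum scaling farther from it. The former gave -0.43 for glycolysis, -0.20 for respiratory genes, -0.27 for amino acid biosynthesis and -0.10 for stress genes. Nitrogen catabolite repression targets were then at -0.17, phosphate genes at -0.24 and the regulators at -0.06. Sulfur and methionine genes were at 0.32, led by MUP1, a methionine permease, at 2.43. Early meiotic genes were at 0.49, with SAE3 at 2.29, MND1 at 2.15 and SPO16 at 1.8, MEI4 at 1.36 and ZIP1 at 1.21, against MSH5 at -3.15 and HOP2 at -1.62.

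Across all genes, 5976 ORFs were eligible in starved cells, with 317 at least 2-fold higher and 247 at least 2-fold lower in the deletion. The median over all of them was -0.04, and equal-sum scaling moved it to -0.18 and gave 256 and 360. Median-of-ratios scaling gave 373 and 198, and upper-quartile scaling 332 and 224. The highest folds were those of SRT1, a cis-prenyltransferase (3.58), RNP1, a ribonucleoprotein (2.75), YLL047W, whose name places it at the same locus (2.65), PIR1, a cell wall protein (2.45), and MUP1. SAE3, INO1, which makes inositol phosphate (2.27), RPS26B, AGP1, an amino acid permease (2.16), and MND1 completed the top 10. The lowest were FIG1 at -7.10, PRM6 at -6.36, YML047W-A at -5.75, FUS2, for cell fusion, at -4.80, MF(ALPHA)2 at -4.78 and PHO23 at -4.53. YNL042W-B at -4.06, MFA2 at -3.80, YER187W at -3.51 and FIG2 at -3.49 followed. Counting error alone gave 0 to 1 such ORFs in 20 draws.

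Some differences between genotypes were present in both conditions. Over 5381 ORFs eligible in each, 29 were at least 2-fold higher in both conditions, where independent lists would share 12.3. For lower ORFs the number was 75, against 3.1. Without the mating and cytosolic ribosomal protein lists, 29 and 55 remained, against 7.3 and 2.2. Across genes, which are not independent replicates, the genotype folds of the 2 conditions had a Pearson r of 0.45 and a Spearman rho of 0.30. The 2 comparisons share no library. INO1 (2.19 and 2.27), MND1, RNP1 (1.93 and 2.75), SAE3, YOL131W (2.41 and 1.85) and GMC2, a meiotic gene (2.14 and 1.69), were among the highest in both. YLL047W (1.8 and 2.65), YGL081W (1.62 and 1.67), ARO10, a decarboxylase (1.65 and 1.61), and YHR137C-A (1.5 and 1.74) completed the 10. Among the lowest in both, FIG1, MF(ALPHA)2, PRM6, PHO23, AGA1, MFA2, YML047W-A, PRM1 and SAG1 were joined by FDC1, a ferulate decarboxylase (-3.01 and -2.81).

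**Figure D3:**
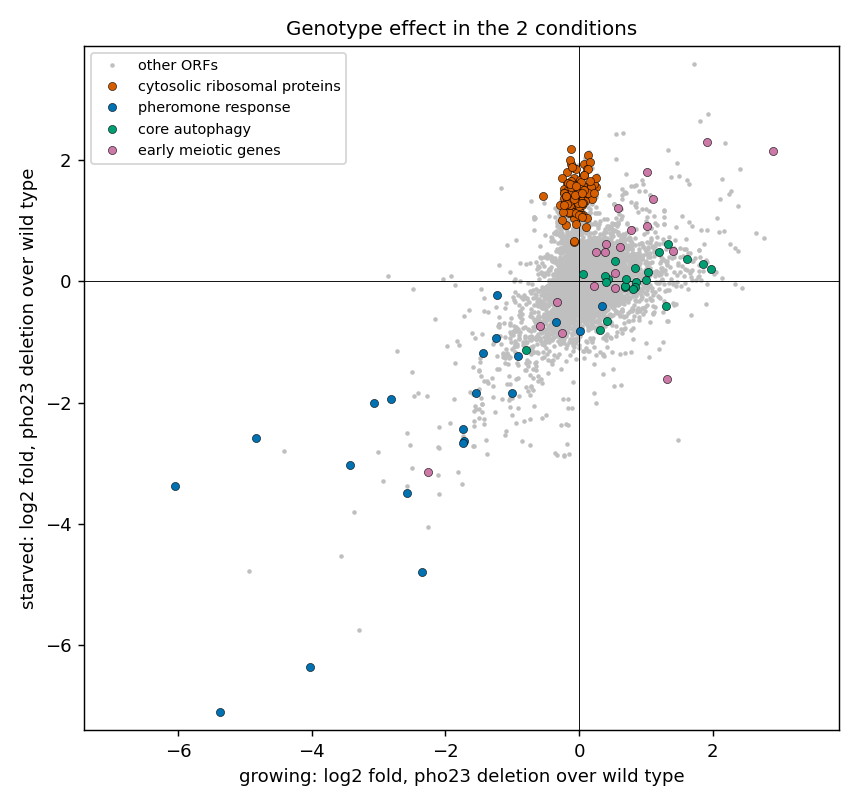
Genotype log2 fold (pho23 deletion over wild type) in growing cells on the x axis and in starved cells on the y axis, with 1 point per ORF of RPKM at least 10 in at least 1 library. Cytosolic ribosomal proteins form a column near 0 in growing cells (median -0.06) and above 0 in starved cells (1.44), while pheromone-response genes lie low on both axes (-1.73 and -2.00).

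Wild type in SD-N had higher transcript levels of nitrogen uptake and autophagy genes, and lower levels of ribosome genes, than growing wild type in YPD. Targets of nitrogen catabolite repression had a median log2 fold of 5.18, with 20 of 21 at least 2-fold higher and MEP3 at 0.40. DAL80, a GATA repressor, stood at an RPKM of 1.88 growing and 911 starved (8.31). GAP1, the general amino acid permease, was at 6.61 and 2085 (8.10), and DAL5, an allantoate permease, at 7.59. PUT4, a proline permease, was at 7.51, MEP2, an ammonium permease, at 7.40 and DUR3, a urea transporter, at 7.02. YKR033C, whose name places it beside DAL80 and which is uncertain for that reason, was at 7.95. SPG4 (7.15), FMP16 (7.04) and MFA1 (6.75) completed the 10 highest. Of the core autophagy genes, 20 of 23 were at least 2-fold higher, with a median of 1.73 (percentile 100). ATG8 was at 3.90, ATG1 at 3.85, ATG29 at 3.27 and ATG7 at 2.94. ATG12 at 0.45, VPS30 at 0.38 and ATG10 at -0.48 were under 2-fold. The selective list had a median of 1.98 with 12 of 16 higher, led by ATG39 at 5.02 and ATG32, the mitophagy receptor, at 3.63. Vacuolar hydrolases were at 2.82, with 11 of 12 higher and PRB1, a protease, at 5.10, APE1 at 4.49 and CPS1 at 4.44.

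Metabolic groups also differed between starved and growing wild type. Sulfur and methionine genes had a median of 4.04 with 16 of 20 at least 2-fold higher, led by SUL1, a sulfate permease, at 6.71, MET28 at 5.62 and MET16 at 4.99. Amino acid biosynthesis was at 1.65, with 28 of 40 higher and ARG3 at 6.03. Stress genes were at 2.76, with 26 of 30 higher, DDR2 at 6.69, HSP78 at 5.12 and HSP12 at 5.04. Early meiotic genes had a median of 1.23 and respiratory genes of 0.73 (0.77 and 0.20 with median-of-ratios scaling). Every cytosolic ribosomal protein gene was at least 2-fold lower, with a median of -2.51, RPS22B at -4.22 and RPL9A at -3.90. Ribosome biogenesis was at -2.01, with 64 of 66 lower, ENP1 at -3.00 and NOP1 at -2.99. Mitochondrial ribosomal proteins were at -1.48, with 37 of 56 lower. Glycolysis was at -1.39, with 13 of 16 lower (8 with equal-sum scaling), ADH1 at -3.18 and PDC1, the main pyruvate decarboxylase, at -2.67. Histone genes were at -1.16, G1 and S phase genes at -0.84 with CLB6 at -2.10 and RNR1 at -2.05, and G2 and M phase genes at -0.53 with CLB1 at -1.43. The lowest of all were DBP2, an RNA helicase (-5.80), INA1 (-4.58), PTR2, a peptide transporter (-4.29), and ASC1, a ribosome-associated protein (-4.27). RPS22B, YOL014W (-3.97), YPR123C (-3.94), RPL9A, RPS9A (-3.86) and BAP3, an amino acid permease (-3.72), followed.

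Of 5956 eligible ORFs in wild type, 1950 were at least 2-fold higher and 795 at least 2-fold lower after starvation, and the median over all of them was 0.53. Ribosomal protein genes held 39.4% of summed RPKM in growing wild type and 8.4% after starvation, which bears on all other values relative to the total. Median-of-ratios scaling set the overall median to 0.00 and gave 1131 higher and 1254 lower. Equal-sum scaling set it to 0.85 and gave 2677 and 601, and upper-quartile scaling set it to 0.25 and gave 1470 and 999. The core autophagy median was 1.25 with median-of-ratios scaling and 2.04 with equal-sum scaling.

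Starvation folds in the deletion correlated with those in wild type and were smaller in several groups. Of 5863 eligible ORFs, 1311 were at least 2-fold higher and 514 at least 2-fold lower, with an overall median of 0.34. With median-of-ratios scaling these were 838 and 926 around a median of 0.00, and with upper-quartile scaling 1029 and 748 around 0.16. Wild type and deletion shared 1199 of the higher and 442 of the lower ORFs. The correlation across genes had r of 0.91 and rho of 0.92. Over all 6034 ORFs eligible in at least 1 library, 1265 were higher in both, against 444.8 for independent lists, and 445 lower in both, against 68.3. The highest in the deletion were DAL80 (7.96), GAP1 (7.73), SPG4 (7.60), YKR033C and PUT4 (both 7.44), DAL3 (7.19), DAL4 (7.13), MEP2 (7.11), SUL1 (6.82) and DAL5 (6.70). The lowest were DBP2 (-5.40), IZH4 (-4.89), INA1 (-4.85), HO, the mating-type endonuclease (-4.21), ADH1 (-4.04), PHO3, an acid phosphatase (-3.98), and TAT1, an amino acid permease (-3.85). MRH1 (-3.45), HXT4, a glucose transporter (-3.43), and TAT2, a tryptophan permease (-3.21), followed.

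Group by group, nitrogen catabolite repression targets had a median of 5.63 in the deletion and a median gene-by-gene difference from wild type of -0.29, with 19 of 21 at least 2-fold higher, GLN1 at 0.54 and MEP3 at -1.36. Core autophagy genes had a median of 1.17 with 14 of 23 higher. ATG8 was at 3.19, ATG1 at 2.15, ATG9 at 2.13 and ATG15 at 1.90, while ATG18 was at 0.08 and ATG10 at -0.83. The selective list was at 1.14 and vacuolar hydrolases at 1.71. Sulfur genes were at 3.53, stress genes at 2.21, amino acid biosynthesis at 1.04 and early meiotic genes at 0.97. Cytosolic ribosomal proteins had a median of -1.02 with 77 of 137 at least 2-fold lower (133 with median-of-ratios and 37 with equal-sum scaling), and ribosome biogenesis -1.0 with 33 of 66 (54 and 21). Mitochondrial ribosomal proteins stood at -1.36 and glycolysis at -1.99. Respiratory genes were at 0.33, turning to -0.01 with median-of-ratios scaling. Cytosolic ribosomal protein genes held 38.6% of summed RPKM in the growing deletion and 20.7% in the starved deletion.

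**Figure D4:**
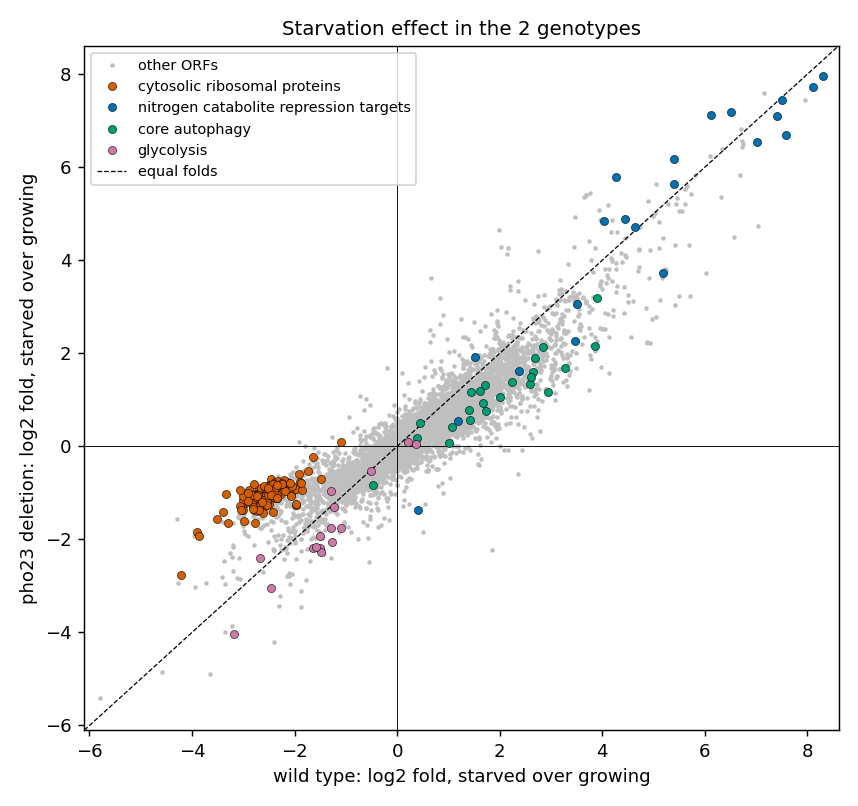
Starvation log2 fold (starved over growing) in wild type on the x axis and in the pho23 deletion on the y axis, with 1 point per ORF of RPKM at least 10 in at least 1 library and a dashed line of equal folds. Cytosolic ribosomal proteins lie above the line (medians -2.51 and -1.02), nitrogen catabolite repression targets near it (5.18 and 5.63), core autophagy genes below it (1.73 and 1.17) and glycolysis genes below it (-1.39 and -1.99).

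Set directly against each other, the starvation folds of the genotypes differed at least 2-fold upward in the deletion for 318 of 6034 ORFs and downward for 329, with an overall median difference of -0.15. Median-of-ratios scaling gave 420 higher and 207 lower around a median of 0.04, and equal-sum scaling 258 and 491 around -0.30. Cytosolic ribosomal proteins had a median difference of 1.49 and core autophagy genes of -0.78, with 6 of 23 at least 2-fold lower in the deletion (4 with median-of-ratios and 11 with equal-sum scaling). ATG7 differed by -1.77, ATG1 by -1.70, ATG29 by -1.58, ATG14 by -1.24, ATG38 by -1.12 and ATG31 by -1.06. For ATG7, ATG29 and ATG14 the starved values of the genotypes lay close together (genotype folds of 0.20, 0.28 and 0.37) and the growing values lay apart. For ATG38 and ATG31 the starved folds (-0.80 and -0.65) were larger in size than the growing ones (0.32 and 0.41), and ATG1 had 1.30 growing and -0.40 starved. The largest positive differences were those of DIA1 (2.96), PTR2 (2.72), AGA1 (2.67), YMR316C-A, which overlaps DIA1 and is uncertain (2.35), RPS26B (2.30), FUS1 (2.26), RPS3 (2.13), MNC1 (2.08), RPL9A (2.07) and YOL014W (2.04). The most negative were those of YMR242W-A (-4.08), HOP2 (-2.94), SNO4 (-2.70), HSP33 (-2.66), HSP32 (-2.64), FMP23 (-2.54), YNL146W (-2.53), YGR164W (-2.50), AGA2 (-2.47) and YML047W-A (-2.45). HSP32, HSP33 and SNO4 are near-identical and uncertain, and YNL146W lies 396 bp from MFA2.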

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

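All tests in this part except that on the 8 pheromone-response genes not yet looked at were chosen only after the result was seen.

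Mating and pheromone-response genes were lower in both deletion libraries, with list medians of -1.73 growing and -2.00 starved. Library scaling is argued against, since the median nearer to 0 was -1.83 after median-of-ratios rescaling. Lower pheromone pathway output in the deletion failed the rule set beforehand, under which fewer than 4 of the 8 genes not yet looked at would count against it. Of these, 3 (PRM3, PRM4 and KAR5) were at least 2-fold lower in both conditions, 1 short of the 4. It is left open only because 8 genes are too few to tell 3 from 4, which was not part of that rule. The medians of the 8 genes were -1.07 growing and -1.03 starved. MATa cells mixed into the wild-type cultures, which would bring a-factor and its response, cannot be told apart from an effect of the deletion, because the starved folds of the 7 a-specific genes spanned 2.88 and a shared baseline in both strains gives such a span too; HMRA1, where reads of the a1 gene would align, was listed at 0 in all 4 libraries, which counts against such cells only if that ORF was counted. An effect of the deletion on part of these genes or a strain variant may also underlie the pattern. This stays open, since each genotype has 1 library per condition.

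Ribosomal protein genes had a median of 1.44 in the starved genotype comparison. Library scaling and reads shared between paralogs are argued against, with a lowest median of 1.30 over the 3 rescalings and a median of 1.49 over 19 single-copy genes. Less advanced starvation of the deletion culture stays open, since a delay need not act on all groups alike. ORFs outside the ribosomal protein and ribosome biogenesis lists that were lower in starved wild type kept a median share of 0.66 of their log2 fold (quartiles 0.49 and 0.90). ORFs that were higher kept 0.72 (0.56 and 0.87), cytosolic ribosomal protein genes 0.40 (0.37 and 0.45) and ribosome biogenesis 0.49. A delay of equal size in all groups is argued against by nitrogen catabolite repression targets at 0.98, mitochondrial ribosomal proteins at 0.93 and glycolysis at 1.32. The ORFs were picked on their wild-type fold, which bears on these shares. A smaller decrease of ribosomal protein transcripts may come from the deletion or from another difference between these cultures, which 1 library each leaves open.

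Core autophagy genes had a median of 0.81 in the growing genotype comparison. At the roughly estimated depth, counting error at low RPKM is argued against for the 8 genes at 2-fold. The interval excluded 1 for each, with a lowest bound of 1.88. These genes were picked for their fold, and the 15 under 2-fold were not part of this check. A culture clearly nearer to nitrogen limitation is argued against by the nitrogen catabolite repression list, with 1 of 21 genes at least 2-fold higher. Its genes highest in starved wild type (DAL80, GAP1, DAL5, PUT4, MEP2 and DUR3) had growing genotype folds from -0.36 to 0.41. The median of -0.23 (-0.12 with a pseudocount of 5) rests partly on DAL1, DAL2, DAL4 and DCG1, neighbours by ORF name. As 9 of 21 genes lay above 0, a slight shift stays open. A culture nearer to glucose exhaustion cannot be told apart from an effect of the deletion, because the tables point both ways: the respiratory median was 0.09 (-0.00 with median-of-ratios scaling), HXT5 was at -0.26 and HSP12 at -0.86, but the general stress median was 0.66 with 9 of 30 genes at least 2-fold higher. Ribosome biogenesis genes had a growing genotype median of -0.20 with 6 of 66 above 0, and cytosolic ribosomal proteins of -0.06 with 48 of 137 above 0. An effect of the deletion, a strain variant or another state of this culture may underlie the pattern, and which of them was not tested.

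The remaining results stood out because the effect had opposite signs in the groups compared, and none of these differences was tested. Amino acid biosynthesis genes had genotype medians of 0.23 growing and -0.37 starved, with a median difference of -0.56. Cytosolic ribosomal proteins were at -0.06 and 1.44, a median difference of 1.49. Ribosome biogenesis genes were at -0.20 and 0.84, a median difference of 0.96. General stress genes were at 0.66 and -0.20, a median difference of -0.82. HOP2, which lies 168 bp from AGA2, had genotype folds of 1.31 and -1.62, a difference of -2.94. GPG1 had 1.25 and -1.01, a difference of -2.26, and ARG3 had 1.05 and -1.25, a difference of -2.30. YMR242W-A had starvation folds of 1.85 in wild type and -2.23 in the deletion, a difference of -4.08, at RPKM values between 1.02 and 11.3.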

How the results depend on the processing

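All 7 alternatives in this part were planned; the core autophagy medians use no filter, so both filter settings were not run for them. Of the main medians and correlations, the starved genotype median of core autophagy, which lay near 0, was the one that changed sign. With median-of-ratios scaling, 1131 ORFs were higher and 1254 lower after starvation in wild type, 838 and 926 in the deletion, and 207 had a lower starvation fold in the deletion; the rescaling sets the overall median to 0. With an RPKM of at least 30, fewer ORFs were eligible, and 132 were higher and 63 lower in the growing deletion, 16 higher and 43 lower in both conditions. Without a filter, 197 were lower in the growing deletion and 142 in both conditions, as low ORFs entered. A pseudocount of 5 gave 140 higher in the growing deletion. The core autophagy median in growing cells was 0.63 with a pseudocount of 5, and in starved cells -0.11 with equal-sum scaling. After starvation of wild type it was 1.94 and 1.52 with pseudocounts of 0.1 and 5, and 1.25, 2.04 and 1.47 with median-of-ratios, equal-sum and upper-quartile scaling. In the deletion it was 1.03 with a pseudocount of 5, and 0.85, 1.33 and 1.0 with these scalings. A larger pseudocount or a change of library factors moves these values by construction; no other cause was tested. All 14 alternative correlations stayed within 0.1. Across all lists and alternatives, 310 medians stayed within 0.1 and 270 moved further, and for named genes 351 and 619. Depth limits short ORFs of low RPKM such as YMR242W-A. An additive fit of genotype and condition over the 4 libraries, which would take the difference between conditions as error, was not run.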

Other observations

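The tests on chromosome ends and on the PHO23 neighbours were written before their results were seen, and leaving out the PAU and COS families was chosen after.

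Transporters, sterol and iron genes add to the picture of both genotypes. Hexose transporters had a growing genotype median of -0.25, with GAL2 at -1.33 and HXT8 at -1.20. With a pseudocount of 5 this median was -0.15, and 0 hexose transporters were at 2-fold between growing genotypes. After starvation the median was -0.33, with HXT4 at -1.87, HXT8 at -1.30, HXT9 at -1.28 and GAL2 at -1.05. HXT8, HXT9 and GAL2 lay under an RPKM of 10, and a pseudocount of 5 left 1 of these 4 at 2-fold. Starvation of wild type gave HXT5, a transporter of slow growth, a log2 fold of 4.09 and the glucose sensor RGT2 2.33. Iron regulon genes had a starvation median of 1.33 in wild type, with 11 of 14 at least 2-fold higher, and 0.65 in the deletion, with 4. With median-of-ratios scaling these were 6 and 3 genes, with medians of 0.87 and 0.36, and with a pseudocount of 5 they were 7 and 3. HMX1, a heme oxygenase, was at 2.44 and CCC2, a copper transporter, at 2.17 in wild type, against FRE1, a ferric reductase, at -1.98. In growing cells FIT3 at 1.91 and FIT2 at 1.33, which encode cell wall mannoproteins, were the 2 iron genes at 2-fold between genotypes. Ergosterol genes had genotype medians of -0.14 growing and -0.29 starved, with none of 23 at 2-fold and ERG3 at -0.99 in starved cells. Proteasome genes were at 0.12 and 0.01 (-0.14 with equal-sum scaling). After starvation of wild type they were at 0.58, with 0.05 under median-of-ratios and 0.89 under equal-sum scaling. LEU2 and URA3, marker genes of this strain, were at 0.26 and 0.50 between growing genotypes. The median of 3 marker genes was 0.26 growing and 0.05 starved, the latter -0.09 with equal-sum scaling. Histone genes had genotype medians of -0.10 and 0.01 (-0.14 with equal-sum scaling).

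Genes near chromosome ends were lower in the deletion. Among 246 ORFs within 20 kb of an end, 44 were at least 2-fold lower and 5 higher in growing cells, and 69 and 0 in starved cells, counted at any RPKM. A pseudocount of 5 left 9 lower in growing and 28 in starved cells, with medians of -0.08 and -0.35. Among those with an RPKM of at least 10, 14 of 77 were lower in growing cells, where 1.5 would be if spread evenly, and 32 of 132 in starved cells, against 5.2. The medians were -0.20 and -0.53, where matched random lists gave -0.00 and -0.11 on average. FDC1, YER187W (-2.10 and -3.51) and COS12, of a subtelomeric family (-1.42 and -2.27), were among the lowest, together with HXT15 (-2.11 and -2.74) and HXT16 (-2.09 and -2.75), which are near-identical and uncertain. PHO89 (-2.51 and -1.50) and ADH7, an alcohol dehydrogenase (-1.87 and -1.94), also lie there. These genes were picked after their values were seen. The PAU family, whose members are near-identical and uncertain, had low RPKM and medians that follow the pseudocount, -0.33 growing and -1.0 starved (-0.48 with a pseudocount of 5 and -1.33 with 0.1), with PAU2 at -1.67 and PAU3 at -1.58 in starved cells. The COS family was at 0.10 and -0.14.

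A hypothesis is that transcript levels near chromosome ends are lower in the pho23 deletion. It predicted a median below the 2.5th percentile of matched random lists in both conditions, and the higher of both percentiles was 0.0. Without the PAU and COS families, the medians over 216 ORFs were -0.20 and -0.50. By distance, the growing and starved medians were -0.00 and -0.17 at 20 to 40 kb (282 ORFs) and 0.05 and -0.00 at 40 to 60 kb (318). They were 0.08 and 0.04 at 60 to 80 kb (326) and 0.06 and -0.04 beyond 80 kb (4806). The pattern may come from the deletion or from another difference between these cultures.

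Another hypothesis was an effect of the marker cassette on neighbouring genes at the PHO23 locus, and 0 neighbours were at least 2-fold changed the same way in both conditions. The neighbours tested were PLS1, at -0.02 and 0.31, and RPS7B, at 0.09 and 1.32. PLS1 had low RPKM values of 7.50 and 7.39 in growing wild type and deletion. RPS7B belongs to the cytosolic ribosomal proteins, whose starved median was 1.44. The test therefore says little about the cassette. RAS2, which was not part of the test, was at -0.01 and -0.24.

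At the mating-type loci, MATALPHA2 had an RPKM of 186 in growing wild type, 129 in the growing deletion, 467 in starved wild type and 291 in the starved deletion. MATALPHA1 and its silent copy at HML carried identical values, 104, 37.3, 267 and 65.1, so their reads cannot be assigned. Whether reads of MATALPHA2 could also come from a copy at HML was not examined. HMRA1 was listed at 0 in all 4 libraries. Of the pheromone-response genes, STE12, the transcription factor of the pathway, was at -1.44 and -1.19, KAR4 at -3.07 and -2.00, and SST2 at -2.81 and -1.94, named after their values were seen. The 8 genes of that list not yet looked at had medians of -1.07 growing and -1.03 starved.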
